A study of Mus musculus with 10 samples.

How the data were processed

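Messenger RNA was measured in tumours from implanted mouse embryonic fibroblasts with RAS and dominant-negative p53. Per the labels' protocols, cells were implanted under the skin, treatment began at 500 mm3, the siRNA formulation was given 5 times a day by the rectal route, and tumours were taken 30 minutes after the last dose. Libraries were made with a stranded mRNA kit and sequenced as single reads of 100 bases. Samples were grouped by their titles into tagged (3 tumours) and untagged (2 tumours) cyclin D1, all given HA siRNA, with 2 lanes per library. Both sequencing runs hold tumours of both groups, but with only group values the run could not be examined.

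Per the series' design text, reads were mapped to the mouse genome MGSCv37 with Bowtie and TopHat, and abundance and differential expression came from Cufflinks. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.8b and Cufflinks 2.1.1. The deposited table has the layout of Cuffdiff, with 1 value for condition C1 and 1 for C2. Its header names no unit, and the values are taken as FPKM as that layout implies, so "FPKM" here means the abundance the authors deposited. Which tumours entered C1 and C2, and which condition is tagged, is not given in the sources used here. The p-values and q-values are those the authors deposited from Cuffdiff. The deposited q differed from a Benjamini-Hochberg adjustment of the deposited p over tested rows by at most 5.17e-07. The deposited GO tables are, per the file headers, from BiNGO, with a hypergeometric test and the whole annotation as reference.

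Of the 27968 rows, 11286 were not tested by Cuffdiff and 1, the mitochondrial genome, was left out for too many reads. A spreadsheet had spoiled 516 cells of the deposited log2 fold and turned 14 gene symbols into dates, none of them called (0). The fold was therefore computed as log2 of the value of C2 over that of C1, with no pseudocount. Of the tested rows, 3055 carry no gene name, 74 of which were called, and 323 carry several gene names because overlapping genes were joined, so that their values cannot be told apart. Rows without a name and shorter than 200 bases hold 59.4% of the sum of C1 values and 60.6% of that of C2. FPKM divides by length, which raises the values of short rows, but the source of this share was not tested. Called rows listed at 0 number 14 in C1 and 8 in C2, and no fold is given for them. The depth of the libraries is unknown. The median log2 ratio of tested rows with at least 1 FPKM was 0.06.

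The tumours could not be tested again without values per tumour. Genes were called at q under 0.05. The lists, 22 in number, the named-gene rule, the tests and most alternatives were fixed before the data were examined. Another 6 lists were chosen after seeing the data. Each symbol was represented by its row with the highest mean, and a joined row counted once per list. A list's median log2 ratio was placed among 10000 random lists of its size, matched on mean expression in 20 bins. Calls adjusted over the list alone are Benjamini-Hochberg adjustments of the deposited p within the list. The background for over-representation was the 13300 named genes with a valid test. List and over-representation code was tested on simulated data with 13300 genes, of which 200 were shifted. With a log2 shift of 0.5, 47 of 50 lists of 20 shifted genes passed the upper percentile bound, with a shift of 1 all 50 did, and with no shift (0) 1 did. Over-representation was found for 38, 50 and 0 of the 50 lists at those shifts. The simulated genes varied independently with a common spread and were called by a fixed cut on the log2 ratio. Over-representation was counted there at an unadjusted Fisher's exact p under 0.05. The simulation therefore checks the code and does not give the error rates or power of the tests reported here.

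Ccnd1 was always named. The 12 highest and 12 lowest log2 ratios were named among called genes with at least 1 FPKM in a condition, leaving out symbols of the forms Gm with a number, Rik and LOC, microRNA and small nucleolar RNA symbols and joined rows. In each list up to 4 called members were named by absolute log2 ratio, or the most abundant member where none was called. A gene at 0 in a condition ranked after the others. Some genes that the rule selects are not reported here. Coordinates are those of the deposited table, on MGSCv37. Alternatives were a q of 0.01, minimums of 1 and 5 FPKM, other adjustments, a 2-fold minimum, pseudocounts of 0.1 and 1, re-centring, unmatched random lists and another background. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.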

Results

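The data were mRNA profiles of mouse tumours grown under the skin of immune-compromised animals from C57BL/6 embryonic fibroblasts carrying an oncogenic RAS and a dominant-negative p53. The 5 tumours were sequenced as 10 samples, since each library was run on 2 lanes. In 3 tumours, from 2 numbered lines, cyclin D1 carried the tag that the siRNA recognises, and in 2 tumours, from 2 other lines, it did not. Animals of both groups received the same siRNA against the HA tag, so that the tag was the labelled difference between them. No line occurs in both groups, so the tag is compared between lines, with 2 lines in each group. Tagged replicates 2 and 3 carried the same line number. The authors' deposited table gives 1 abundance value for each of 2 conditions, named C1 and C2, with Cuffdiff's p and q. Nothing in the table or the sample labels states which condition is tagged, so each direction below is that of C2 relative to C1, and none is assigned to the tag. There are no values per tumour, so no SD or n accompanies any value, and the depth is unknown. Whether Cuffdiff took tumours or lanes as replicates is not given in the sources used here. How far q reflects the spread between tumours is therefore unknown.

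The first question was which genes differed between the conditions. The table holds 27968 rows, of which 16681 had a valid test. A q under 0.05 in the authors' deposited table was given to 1187 rows, of which 700 were higher and 487 lower in C2, and 1077 of them differed at least 2-fold. With 1 row kept per gene symbol, 659 named genes were called higher in C2 and 450 lower, out of 13300. At an unadjusted p under 0.05 there were 2857 rows. The smallest p Cuffdiff gave, 5e-05, was shared by 500 rows, so genes at that value cannot be ranked by p.

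Cyclin D1, the protein that carried the tag in the tagged tumours, was not called. Ccnd1 (XLOC_023532, chromosome 7, 152115787 to 152125830, MGSCv37) stood at 161 FPKM in C1 and 243 FPKM in C2 in the authors' deposited table, a log2 ratio of 0.59 with p = 0.03045 and q = 0.218. Ccnd1 values cover the transcript with and without the tag, which the table does not separate.

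By log2 ratio without a pseudocount, the genes furthest apart among those the rule names were higher in C2. Rgs8, lower in C2 (-6.44), lay further from 0 than BC006965 and the smaller rises given here. Col9a2, a chain of the cartilage collagen type IX (XLOC_017049, chromosome 4, 120712170 to 120727930), rose from 0.0992 to 20.1 FPKM in the authors' deposited table, a log2 ratio of 7.67 (q = 0.004205). Its partner chain Col9a1 had a log2 ratio of 6.64. Sox10, a transcription factor of neural crest and some glandular epithelia, rose from 0.672 to 75.9 FPKM by the same table. Lcn2, an iron-carrier-binding secreted protein (XLOC_014028, chromosome 2, 32240154 to 32243259), rose 63.4-fold, from 48.1 to 3049 FPKM in the authors' deposited table. Wfdc18, a secreted protein of the whey acidic protein family, rose 81.1-fold, from 7.39 to 599 FPKM in that table. The other genes named by the rule were BC018473 (log2 ratio 7.27), the proton pump subunit Atp6v1b1 (6.98), the glutathione peroxidase Gpx2 (6.49), the nucleoside transporter Slc28a3 (6.45), BC006965 (6.35), Faim2 (6.08) and the transcription factor Gata4 (5.88). The order rests partly on values near 0 in C1: with a pseudocount of 1 the log2 ratio was 4.26 for Col9a2, 4.37 for Atp6v1b1, 2.80 for Slc28a3, 3.78 for BC006965, 3.87 for Faim2 and 2.37 for Gata4, against 6.16 for Wfdc18, 5.98 for BC018473 and 5.96 for Lcn2.

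Among the genes furthest lower in C2, Rgs8, a regulator of G-protein signalling (XLOC_000452, chromosome 1, 155500166 to 155544795), fell by 6.44 on the log2 scale, from 6.81 to 0.0785 FPKM in the authors' deposited table (q = 0.001668). The myogenic factor Myf6 had a log2 ratio of -4.98, and the muscle proteins Tnnc2 and Ttn had -3.86 and -3.86. Itga4, the alpha 4 integrin, went from 17.3 to 1.03 FPKM in the authors' deposited table. The remaining genes were Rab3c (-4.90), Cilp2 (-4.47), Glycam1 (-4.44), Gad2 (-4.38), Atp2a3 (-3.99), the channel Nalcn (-3.77) and the hair keratin Krt25 (-3.76). With a pseudocount of 1 the log2 ratio was -2.86 for Rgs8, -1.32 for Rab3c, -1.14 for Cilp2, -1.59 for Gad2, -1.33 for Nalcn, -2.90 for Myf6, -1.64 for Ttn and -1.65 for Krt25, against -3.72 for Tnnc2.

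**Figure D1:**
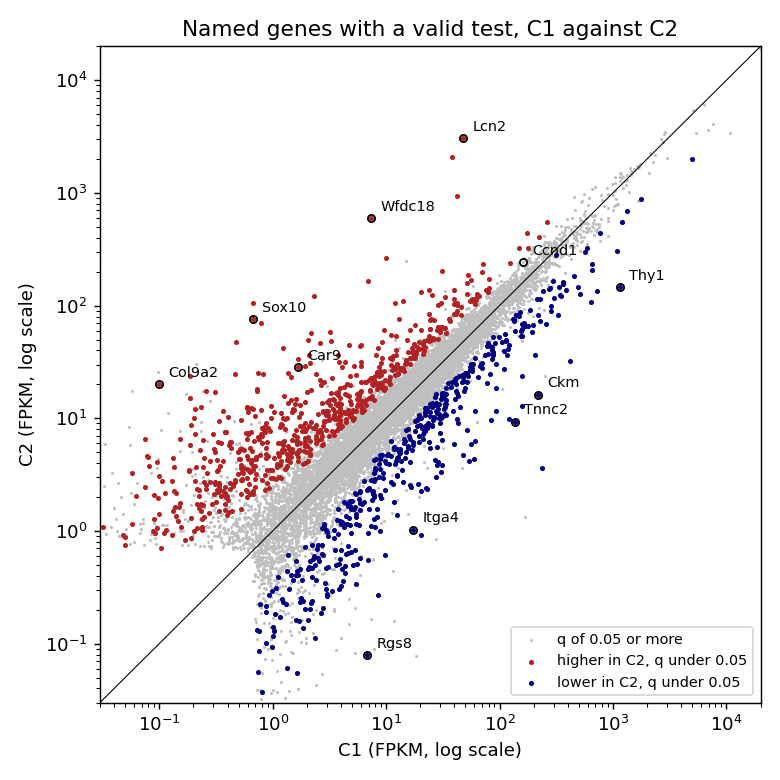
FPKM of each named gene with a valid test in C1 (horizontal, log scale) and C2 (vertical, log scale), from the authors' deposited table; red and blue points had q under 0.05 and the line marks equal values, and genes at 0 in a condition are left out. Lcn2 (48.1 and 3049) and Sox10 (0.672 and 75.9) lie far above the line and Rgs8 (6.81 and 0.0785) far below it, while Ccnd1 lies near it.

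The second question was how groups of genes chosen for this tumour and treatment behaved. Interferon-stimulated genes were higher in C2, with 13 of 26 measured members called higher and 0 lower (22 higher when adjusted over the list alone). Their median log2 ratio was 1.35, at percentile 100 of 10000 random lists matched on expression. The antiviral enzyme Rsad2 rose 8.69-fold, to 4.35 FPKM, and the interferon regulatory factor Irf7 from 5.17 to 29.0 FPKM in the authors' deposited table. With a pseudocount of 1 the log2 ratio of Rsad2 was 1.83, against 3.12 without. Isg15 and Oasl2 had log2 ratios of 2.29 and 2.16. Hypoxia and glycolysis genes were also higher, with 13 of 19 called higher and 0 lower (16 adjusted over the list alone) and a median of 1.13 at percentile 100. Car9, a carbonic anhydrase induced by low oxygen, rose 17.1-fold, and the prolyl hydroxylase Egln3 rose 7.76-fold, from 14.1 to 110 FPKM in the authors' deposited table. Ndrg1 and Adm had log2 ratios of 1.81 and 1.63. Epithelial junction and luminal genes, a list chosen after seeing the data, moved in the same direction as both lists, with 20 of 24 called higher and a median of 3.39.

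Extracellular matrix and fibroblast genes were lower in C2. Of 22 measured members 13 were called lower and 0 higher (16 lower when adjusted over the list alone), with a median of -1.02 at percentile 0. At q under 0.01 the number called lower was 7. The epithelial junction and luminal genes moved in the opposite direction (median 3.39). The surface glycoprotein Thy1 went from 1154 to 147 FPKM and the gelatinase Mmp2 from 495 to 146 FPKM in the authors' deposited table. Lum and Postn had log2 ratios of -1.90 and -1.48. For Col1a1 the deposited fold and the ratio of the deposited values differ (-1.07 against -0.15 on the log2 scale), and it is one of 19 tested rows where they do by more than 0.01. Skeletal muscle markers showed the lowest median of the fixed lists, -3.28 at percentile 0, with 13 of 19 called lower and 0 higher (14 adjusted over the list alone). Ckm, the muscle creatine kinase, went from 217 to 16.2 FPKM and Myl1 from 59.5 to 4.39 FPKM in the authors' deposited table.

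Cell-cycle lists moved less. All 23 S-phase and E2F target genes had higher values in C2, and 3 were called higher (Rrm2, Mcm5 and Uhrf1, log2 ratios of 1.18, 1.10 and 1.06) and 0 lower. For this list 5 were called when adjusted over the list alone, with a median of 0.52 and percentile 100. All 23 mitotic genes also had higher values in C2, and 1 was called higher (Mki67, log2 ratio 1.01), with 3 adjusted over the list alone, a median of 0.54 and percentile 100. None of the 16 measured D cyclins, CDKs and inhibitors was called, nor with adjustment over the list alone (0), with a median of 0.12 at percentile 68.5. Its most abundant member, Cdkn2a, stood at 604 and 471 FPKM in the authors' deposited table (q = 0.572).

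Cell-death lists had few or no calls. Of 15 caspases and apoptosome genes 1 was called higher, the inflammatory caspase Casp1 (log2 ratio 1.58), and 1 lower, Casp4 (-1.45), with 2 and 1 adjusted over the list alone and a median of -0.02 at percentile 20.9. None was called, in either adjustment (0), among 15 Bcl2 family genes (median 0.06, percentile 50.1), 14 death receptors, ligands and adaptors (-0.05, percentile 19.4) or 21 p53 target genes (0.18, percentile 83.0). Their most abundant members had q of 0.908 (the joined row Bcl2l2,Pabpn1), 0.930 (Tnfrsf1a) and 0.857 (Bax) in the authors' deposited table.

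Signalling and stress lists were mixed. Of 19 RAS-ERK output genes 3 were called higher (Phlda1, Myc and Dusp4, of which Phlda1 rose 3.49-fold and the others had log2 ratios of 0.90 and 0.85) and 1 lower (Spry1, log2 ratio -1.09), with 3 and 1 adjusted over the list alone and a median of 0.29 at percentile 99.7. Of 16 endoplasmic reticulum and amino acid stress genes 1 was called higher, the lipoprotein receptor Vldlr (1.16), with 1 adjusted over the list alone and a median of 0.31 at percentile 99.0. Against random lists not matched on expression, the percentiles of these lists were 96.0 for RAS-ERK output and 96.5 for stress genes, inside the central 95% of lists. Of 18 immediate early genes 3 were called lower, the orphan nuclear receptors Nr4a3, Nr4a2 and Nr4a1 (-3.08, -1.56 and -0.91, with -1.54 for Nr4a3 at a pseudocount of 1), while the list's median was 0.07 at percentile 52.0 and 2 members were higher and 3 lower when adjusted over the list alone.

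Markers of other cell types that a dissected tumour can hold had medians of either sign. Of 6 measured lymphocyte and NK markers 3 were called lower, among them the B-cell receptor genes Cd79a and Cd79b (log2 ratios of -3.24 and -2.91), with 3 adjusted over the list alone and a median of -2.89 at percentile 0.01; Cd79b was at 3.86 FPKM in C1 in the authors' deposited table. Of 16 macrophage markers 1 was called higher, Cd14 (1.13), with 1 adjusted over the list alone and a median of -0.07 at percentile 15.6. Of 9 neutrophil markers 1 was called higher, Ltf (3.36), which epithelia also make, against a median of -0.61 at percentile 1.36 and 1 adjusted over the list alone. Of 13 endothelial markers Cdh5 was called higher (0.90) and Tek lower (-1.53), 1 each also when adjusted over the list alone, with a median of -0.51 at percentile 0.05. Of 15 keratinocyte and skin markers Dsp was called higher (1.64) and Lor and Krt10 lower (-2.95 and -1.66), with 4 and 2 adjusted over the list alone and a median of 0.40 at percentile 97.1. That median describes no common shift, since 8 members were higher and 7 lower, with quartiles of -2.29 and 1.82 and a mean of -0.62. Of 9 adipocyte markers Lpl and Car3 were called lower (-1.22 and -0.94), 2 also when adjusted over the list alone, with a median of -0.58 at percentile 0.09. None of 3 erythroid and blood rows was called, in either adjustment (0; median 0.33, percentile 82.5), and the joined row Hba-a1,Hba-a2 had q = 0.263 in the authors' deposited table. Of 5 sex-linked genes Xist was called higher, from 16.2 to 60.9 FPKM in the authors' deposited table, 1 also when adjusted over the list alone, and the list's median, set by its Y-linked members, was -2.56 at percentile 0. With a pseudocount of 1 the log2 ratio was -1.36 for Cd79a, -1.68 for Cd79b, 2.06 for Ltf, -0.96 for Tek and -1.90 for Lor. At q under 0.01 the called members were 1 for RAS-ERK output genes, 1 for adipocyte markers and 0 for mitotic genes, caspases and apoptosome, endothelial markers, and lymphocyte and NK markers.

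**Figure D2:**
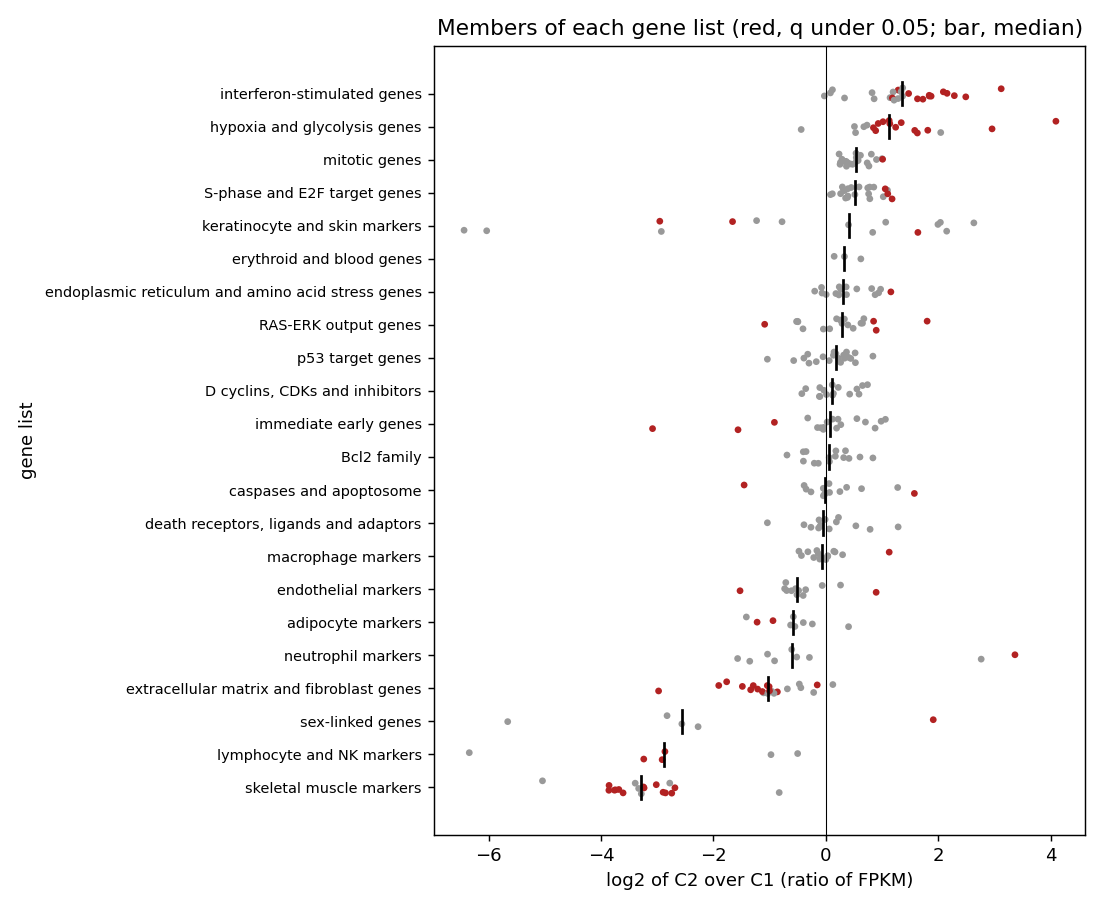
Log2 ratio of C2 over C1 (horizontal) of each measured member of the gene lists (vertical, ordered by median); red points had q under 0.05 in the authors' deposited table, grey points did not, and black bars are medians. Skeletal muscle markers (median -3.28) and extracellular matrix and fibroblast genes (-1.02) lie left of 0, and interferon-stimulated genes (1.35) and hypoxia and glycolysis genes (1.13) right of it.

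Over-representation among called genes was tested with a one-sided Fisher's exact test per list and direction, adjusted by the Benjamini-Hochberg method over 44 tests, of which 5 passed. Among genes called higher in C2 the exact test passed for hypoxia and glycolysis genes (13 of 19, 68.4% against 4.95% of all tested genes, adjusted p = 2.92e-12) and interferon-stimulated genes (13 of 26, adjusted p = 6.08e-10). Among genes called lower the exact test passed for skeletal muscle markers (13 of 19, 68.4% against 3.38%, adjusted p = 6.37e-14), extracellular matrix and fibroblast genes (13 of 22, 59.1%, adjusted p = 5.32e-13) and lymphocyte and NK markers (3 of 6, adjusted p = 0.00627). At q under 0.01 the lymphocyte and NK list no longer passed (adjusted p of 1). Genes are not independent replicates, so these p-values describe the libraries compared.

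The last question was what the authors' gene list and GO enrichment rest on. All 1187 rows of their list were the rows with q under 0.05, in either direction. Their GO test used 1004 genes of the list against the whole annotation of 28912 genes, not the genes measured in the tumours, and returned 919 terms. Their selection of 28 terms covers development and cell death. For nervous system development the authors' deposited table gives 96 genes of the list among 994 (p = 1.2562e-19), for vasculature development 42 among 276 (p = 8.2632e-16) and for mammary gland development 18 among 86 (p = 7.6337e-10). For apoptosis its exact hypergeometric test gives 43 among 472 (p = 1.0704e-08) and for regulation of programmed cell death 59 among 648 (p = 1.9851e-11). The p-values recomputed from the gene numbers differed by at most 2.15e-05 on the log10 scale. Of the apoptosis genes 31 were higher and 12 lower in C2, or 72.1% higher against 59.4% of all symbols called. A two-sided Fisher's exact test found no difference (adjusted p = 0.510 over the 28 terms), which does not show that the shares are equal. Of the mammary gland development genes 12 were higher and 6 lower (Fisher's exact test, adjusted p = 0.832), and of the vasculature development genes 21 were higher and 21 lower (adjusted p = 0.510).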

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

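Use of the deposited fold and the count without muscle and epithelial genes were chosen after seeing the data. No paired analysis was possible because the table gives only a value per condition. For the same reason leaving out each replicate, the sequencing run as a covariate and averaging tagged replicates 2 and 3 were not run, and depth is unknown. The count of called rows stayed within 1.5 times of 1187 under 10 of the other settings, from 832 at 5 FPKM to 1187, and was 1142 without muscle and epithelial genes. The share higher in C2 ranged from 58.7% to 62.7%. At q under 0.01, where fewer genes pass by construction, 702 rows were called, 440 of them higher in C2 and 694 at least 2-fold apart. The same 702 rows remained of the authors' list, by definition, since that list is the rows with q under 0.05. At that threshold 16 of the 72 genes that the naming rule selects lost their call.

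Called members at q under 0.01 were 1 of the RAS-ERK output genes, 1 of the adipocyte markers, 7 of the extracellular matrix and fibroblast genes, and 0 of the caspases, endothelial, lymphocyte and NK, and mitotic lists. With a 2-fold minimum they were 2 for RAS-ERK output genes, 1 for adipocyte markers and 1 for endothelial markers. At q under 0.01 the over-representation of immediate early genes among lower genes passed Fisher's exact test (adjusted p = 0.0365) and that of lymphocyte and NK markers did not (adjusted p of 1). Against random lists not matched on expression, percentiles were 96.0 for RAS-ERK output genes and 96.5 for endoplasmic reticulum and amino acid stress genes, no longer beyond the bound, and 99.0 for keratinocyte and skin markers, now beyond it. The cause was not tested. A pseudocount of 1 shrank the log2 ratios of genes near 0 in a condition, as from 5.88 to 2.37 for Gata4 and from -4.47 to -1.14 for Cilp2. None (0) of the list medians or named genes changed sign among those called or beyond the percentile bounds.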

Other observations

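The epithelial, mammary, myoepithelial, mesenchymal, embryonic muscle and X-linked lists were chosen after seeing the data, as were the tests of fat, of mesenchymal genes and of muscle; for the X-linked genes the prediction preceded their values, but the numbers of expression bins reported were settled after a first result. Genes of epithelial junctions and of luminal mammary cells were higher in C2, with 20 of 24 measured members called higher, 0 lower, 22 adjusted over the list alone, and a median log2 ratio of 3.39. The adhesion protein Epcam rose from 12.0 to 105 FPKM, the E-cadherin gene Cdh1 from 3.86 to 31.5 FPKM and the transcription factor Elf5 from 1.23 to 42.1 FPKM in the authors' deposited table, whereas Krt18 stood at 516 and 514 FPKM. Of 15 mammary secretory genes 9 were called higher (9 adjusted over the list alone, median 2.71), among them the milk protein gene Csn3, from 37.9 to 2066 FPKM, and Trf, from 41.9 to 935 FPKM in the authors' deposited table. The milk protein gene Csn2 was not called, at 2.36 and 0.824 FPKM there. Glycam1, another milk protein gene, which this list does not hold, fell from 20.1 to 0.929 FPKM (q = 0.0131) in the authors' deposited table. None of 8 myoepithelial genes was called (0; 0 higher and 1 lower adjusted over the list alone; median -0.70). The epithelial and mammary secretory lists were drawn up after such genes had been seen to differ, so their counts are not independent evidence, and the genes named in this part were chosen after their values were seen.

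For the luminal mammary genes, whole mammary gland of the host in the C2 tumours would bring fat. The adipocyte list had a median log2 ratio of -0.58 (distribution-free 95% interval -1.22 to -0.24). This cannot exclude whole gland in C2, since fat in the C1 tumours would also lower the ratio. Adipoq stood at 8.55 FPKM in C1 and 5.73 FPKM in C2 (q = 0.580) in the authors' deposited table. Of 15 mesenchymal regulators 12 had lower and 3 higher values in C2, 0 of them called in either adjustment, with a median of -0.46 (interval -0.55 to -0.003) at percentile 0 of matched random lists. That median lay 0.56 above that of the extracellular matrix list (two-sided permutation p = 0.0054). For the libraries compared, this argues only against a replacement of mesenchymal by epithelial cells that lowers both lists alike. The permutation shuffled genes, which are not independent replicates, so its p does not measure the spread between tumours. A replacement with unequal lowering, host gland with or without its fat and epithelial traits of the tumour cells themselves stay open. The tag was not tested, since the tagged condition is not identified.

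For the skeletal muscle genes, 19 of 19 markers were lower in C2. Muscle tissue of the host in the C1 tumours could give this, by about the same factor for each marker. The interquartile range of the markers, 0.84 on the log2 scale, lay at percentile 44.7 of random lists of called lower genes, whereas the test required a range below that of 95% of them. The test decides little: lists of genes that were not called spread by 0.488, slightly over the 0.485 that had to be undercut, so markers with only that spread would miss the bound about as often as meet it. That comparison was added after the percentile was known, and the margin is small. Of 4 embryonic and regenerating muscle genes 1 was called lower, Myh3, with 3 adjusted over the list alone and a median of -3.26. That median rests on low values, since Myh3, Myh8 and Myog stood at 0.746, 0.907 and 3.05 FPKM in C1. The most abundant member, Chrna1, stood at 72.9 FPKM in C1 and 52.5 FPKM in C2 (q = 0.520) in the authors' deposited table. Muscle tissue and muscle-like tumour cells cannot be told apart here.

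For Xist, higher in C2, and the Y-linked genes, lower but not called, unequal shares of male and female cells in the conditions may be the source. Eif2s3y stood at 31.9 and 5.40 FPKM (q = 0.534) and Kdm5d at 2.72 and 0.0539 FPKM (q = 0.661) in the authors' deposited table. The median log2 ratio of 4 X-linked genes that escape inactivation was 0.21, at percentile 97.6 of random lists of X-linked genes matched on expression in 20 bins. With 4 bins, run first, the percentile was 96.5, and with 10 bins 98.0. Among matched random lists of all genes it was only 72.8, the median of X-linked genes being -0.13. The evidence from the escape genes is weak, since 2 of the 4 were higher and 2 lower, and none (0) was called in either adjustment.

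Of the named genes with at least 5 FPKM in a condition and over 10-fold apart, 101 were called and 42 were not. Krt6b stood at 7.82 and 0.0904 FPKM with q = 0.579, and Pvalb at 27.7 and 0.841 FPKM with q = 0.535, in the authors' deposited table. For genes such as these the deposited test allowed a wide spread, and its source cannot be told from values per condition. On chromosome 12 the median log2 ratio of 460 genes was 0.43 and 12.8% were called, against 0.25 and 9.12% on chromosome 11, the next highest median. The next highest share called was 10.7%, on chromosome 15 (median 0.21).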
